A study of Rattus norvegicus with 6 samples.

How the data were processed

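The data were droplet-based single-cell RNA libraries of rat, 4 from the right striatum (control, ICH, ICH with young MSCs, ICH with old MSCs) and 2 from adipose MSCs (young, old), with 1 library per group as the sample labels give them. Per the file headers and their whole-number values, the deposited matrices hold raw counts of UMIs per gene and cell barcode, in the unit count. According to the submitters' processing notes they were made with Cell Ranger 8.0.0 on the rat build mRatBN7.2, and genes were used under the symbols and NCBI gene identifiers of the files. All striatal libraries are labelled male, which the section of other observations takes up.

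Libraries held 15947, 13198, 12271, 12704, 8340 and 7427 barcodes (control, ICH, ICH with young MSCs, ICH with old MSCs, young MSCs, old MSCs) at medians of 3896, 4019, 5561, 6172, 24495.5 and 19810 UMIs. Barcodes with fewer than 300 genes (33, 14, 18, 23, 19 and 6) or with more than 20% of UMIs from mitochondrial genes (283, 189, 457, 298, 257 and 254) were left out. Doublets were scored per library with Scrublet as built into scanpy 1.11.5, with exact neighbours, and those above its automatic threshold were removed. Where that threshold marked under 0.5% of cells, as in the MSC libraries (0.0619% and 0.0139%), the highest scores were removed up to 0.8% per 1000 cells. This removed 211, 163, 149, 233, 523 and 412 cells, or 1.35%, 1.25%, 1.26%, 1.88%, 6.47% and 5.74%. Free RNA was not estimated from empty droplets here. Instead, each gene in a class has a background ratio, its UMIs per cell over the median UMIs per cell of the other named classes, and 2 or more is called above background.

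Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and the 15 nearest neighbours were clustered with Leiden at resolution 1 over the 4 striatal libraries together, without integration. Of 10 seeds the partition of highest modularity was used (0.9316, lowest 0.9306). Clusters were named from 19 marker lists (of 23 set beforehand, 4 were merged into 2 and 2 left out) by mean log2 enrichment over the median of the other clusters with a pseudocount of 5 CPM. A name required a score of at least 1.5, a margin of 0.5 over the next type, at least 3 detected markers and no other type with more markers among the 10 leading genes. Clusters with a median depth below 0.333 of the library median also needed a marker among those genes. Clusters of at least 60 cells that failed on margin, markers or leading genes were split again at resolution 0.5. Names end in "-like" because they rest on these markers. MSC libraries were clustered together in the same way, and cells with at least 4 myeloid markers were left out of the comparison (24 old cells). The naming thresholds, the splitting of clusters, the choice among seeds and the exact neighbours were chosen after seeing the data. Marker lists, gene lists, comparisons and the named-gene rule were fixed before the data were examined.

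Groups were compared as sums of UMIs per library and class, in classes of at least 100 cells in both libraries. Each group has 1 library, so no test was made and no gene was called changed. Shares have exact (Clopper-Pearson) binomial 95% intervals, sums have exact Poisson 95% intervals and folds have exact conditional binomial 95% intervals. The class totals behind these set the precision, from 450818 UMIs in neutrophil-like cells of ICH with young MSCs to 54785259 in macrophage-like cells of ICH with old MSCs, and 194290178 in young MSCs. A gene with 0 UMIs in a library was set against 3 counts in that library to give a lower bound on the fold. Of 33 gene lists, those that apply to a class were summarised as the number of members at least 1.5-fold higher or lower and as the median log2 ratio, with the central 95% of 500 Poisson resamples. A list's percentile among 10000 random lists of the same size, matched on expression, serves as description only. Members needed at least 50 UMIs over both libraries or were not measured.

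Genes were named by size. Eligible genes had at least 50 UMIs over both libraries, at least 20 CPM in 1 of them, a gene symbol that is not a placeholder or of a ribosomal, mitochondrial or hemoglobin gene, and a class level of at least 0.1 of the highest other named class. They were ranked by the interval bound nearest to 1, and the leading 8 in each direction were taken for microglia-like cells, 4 for other classes in ICH against control, 3 for infused against ICH and 12 for MSCs. Up to 4 members per list and Csf1 and Csf1r in every class were added. List members and other genes given beyond these in the text were chosen after values were seen. The share of MSCs with a Csf1 UMI was taken after thinning each cell to 5000 UMIs without replacement.

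The calculation was tested on simulated data with known folds, drawn at the depth of each comparison. Class sums were drawn with Poisson spread, which the intervals assume, so coverage near 95% checks the calculation only. Spread between cells, clusters and rats was not simulated. For microglia-like cells of ICH against control (13334 genes), intervals covered the true value in 95.4% of unchanged genes, 1.92% of which passed 1.5-fold. Of genes with true folds of 1.5, 2 and 4, 45.1%, 98.5% and 100% passed it. For young MSCs against ICH (14431 genes) these values were 95.5%, 1.40%, 52.5%, 100% and 100%, for old MSCs against ICH (13969 genes) 95.5%, 1.39%, 53.2%, 94.3% and 100%, and for MSCs (16839 genes) 95.4%, 0.932%, 39.7%, 98.6% and 100%. Thinning of simulated cells gave a share of 46.5% where 46.5% was expected.

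Alternatives set beforehand covered the gene minimum (200, 1000, or 2000 in MSCs), a mitochondrial limit of 10%, doublets kept, resolutions 0.5 and 2, each library clustered alone, a median-of-ratios factor, the mean of per-cell CPM, a minimum of 200 UMIs, a denominator without hemoglobin, mitochondrial and ribosomal protein genes, cells outside cycling clusters, and for Csf1 no thinning, thinning to 2000 UMIs and at least 2 UMIs. Alternatives chosen after seeing the data were doublets removed at the expected rate, shares of named cells only, cluster 3 added to macrophage-like cells, microglia-like cells of at least 5000 UMIs, list members above background only, cluster 8 alone for macrophage-like cells and the partition of lowest modularity. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 (Leiden) and matplotlib 3.10.9. The base seed was 1, and Leiden was run from 10 seeds.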

Results

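Droplet-based single-cell RNA counts were analysed from 6 rat libraries, 4 of the right striatum and 2 of adipose mesenchymal stromal cells (MSCs). The striatal groups were control, collagenase-induced intracerebral haemorrhage (ICH), ICH with infused young MSCs and ICH with infused old MSCs. The remaining groups were the young and the old MSCs themselves, labelled 1 month and 12 months old, read here as the age of the donors. Their culture and passage are not given in the sources used here. Infusion was 24 h after the haemorrhage and sampling 72 h after infusion, in recipients 8 to 10 weeks old. The sampling times of control and untreated ICH are not given in the sources used here. A label of MSC injection stands on all 6 libraries and was applied here only to the 2 groups whose titles name an infusion. Each group had 1 library, so differences between groups have no replicate check and no test was run. Total depth was 106245335 UMIs in control, 120476079 in ICH, 126612293 in ICH with young MSCs, 147377531 in ICH with old MSCs, 215795095 in young MSCs and 169390063 in old MSCs. After filtering, 15440, 12841, 11663 and 12165 striatal cells were kept in the same order, at medians of 3947.5, 4003, 5801 and 6242 UMIs per cell. The young and old MSC libraries kept 7560 and 6761 cells at medians of 24446 and 19753 UMIs. Expression is given as CPM, UMIs scaled to the same total in the summed cells of each class, and every interval covers counting error only.

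The first question was which cells the striatum held after haemorrhage. Macrophage-like cells made up 19.7% (95% interval 19.1 to 20.4) of kept cells in ICH and 0.311% (0.229 to 0.412) in control. Over the alternative settings of filtering and clustering these shares ranged from 4.90% to 36.9% and from 0.275% to 1.13%. Neutrophil-like cells were 3.10% in ICH against 0.123% in control (ranges 1.06% to 3.31% and 0.105% to 0.596%). T/NK cell-like cells were 1.64% against 0.408%, and dendritic cell-like cells 1.74% of ICH (range 0.361% to 1.81%). The number of control cells named dendritic cell-like went from 0 to 22 over the settings, and 34 cells of a control-rich unnamed subcluster scored highest for dendritic cells. In turn, 49 of the 63 control T/NK cell-like cells were in a subcluster led by mast cell and basophil protease genes. Microglia-like cells were 15.3% (14.7 to 16.0) against 9.16% (8.71 to 9.63). Different clusters held them in each library, cluster 19 (72.9%) and a smaller, shallow cluster (21.3%) in control and clusters 4 (47.4%) and 6 (49.9%) in ICH. A shallow unnamed cluster with macrophage markers, cluster 3 at a median of 1474 UMIs, added 14.6% of ICH cells and 0.00648% of control cells. Microglia-like, macrophage-like and cluster 3 cells together were 49.6% (48.8 to 50.5) of ICH and 9.48% (9.02 to 9.95) of control.

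Cells of the oligodendrocyte lineage and of vessels also had unequal shares. OPC-like cells were 13.9% (13.3 to 14.5) of ICH cells against 1.47% (1.29 to 1.67) of control cells, while oligodendrocyte-like cells were 7.62% (7.17 to 8.10) against 16.2% (15.6 to 16.8). Endothelial-like cells were 1.53% (1.32 to 1.75) against 11.0% (10.5 to 11.5; range over settings 7.90% to 16.3%), fibroblast-like cells 4.24% against 0.194%, and neuron-like cells 8.04% (7.57 to 8.52) against 16.1% (15.6 to 16.7). The control library also held smooth muscle-like cells at 4.86%, of which ICH had 0 to 100 cells over the settings, and with at least 1000 genes per cell the shares were 1.89% in control and 0.968% in ICH. Choroid plexus-like cells were 7.39% against 0.576%, and the control share reached 21.3% with at least 1000 genes and 32.5% at resolution 0.5. Unnamed parts of cluster 2, a cluster led by pituitary hormone, defensin and hemoglobin genes at a median of 1140 UMIs, made up 16.2% of control cells and 1 cell of ICH. Whether the control striatum was dissected or perfused like the others is not given in the sources used here. Shares are parts of a whole, so these control-rich cells lower every other share of the control library.

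**Figure D1:**
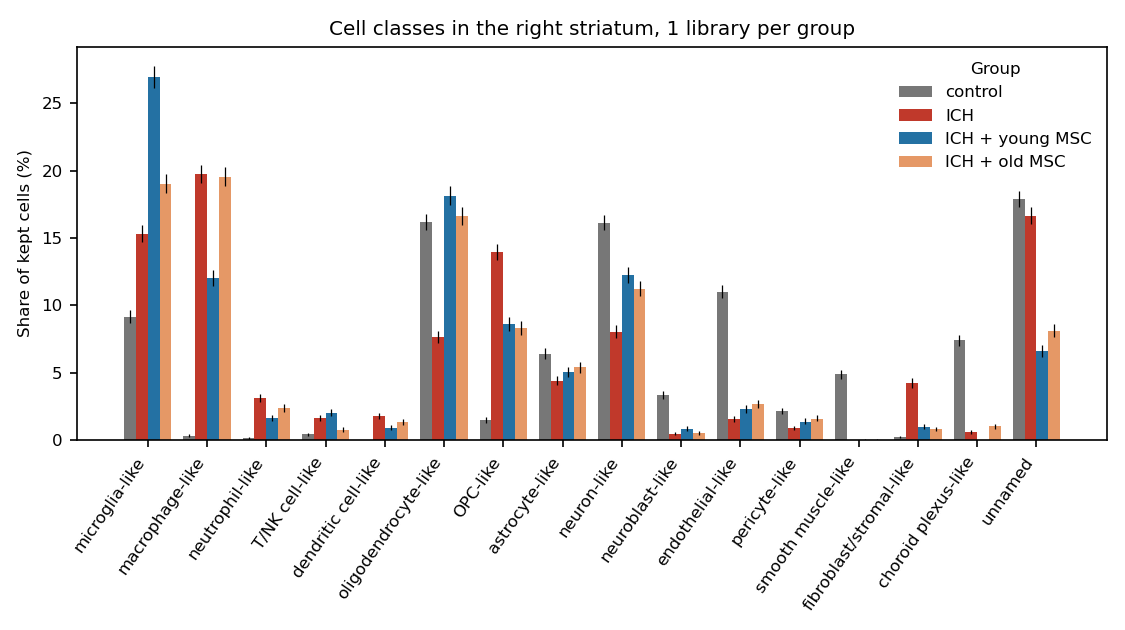
Share of kept cells (%, vertical axis) in each cell class of the 4 striatal libraries. Bars give 1 library each and lines are exact 95% binomial intervals that cover counting error only.

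To ask how microglia differed after haemorrhage, summed counts of 1967 microglia-like cells of ICH were compared with those of 1415 microglia-like cells of control (medians of 4690 and 5771 UMIs). The median gene was 0.13 log2 units lower in ICH (0.00 after a median-of-ratios scaling), and relative to it the medians of the homeostatic and disease-associated lists below are -1.45 and 2.87. Of 13 homeostatic microglia genes, 12 were at least 1.5-fold lower (median log2 ratio -1.59 (-1.61 to -1.53), percentile 0 among 10000 random lists matched for expression). Most of these genes also served to name the cells. The purinergic receptor P2ry12, which guides microglial processes, was at 227 against 477 CPM, Tmem119 at 77.3 against 479.7 CPM and the fractalkine receptor Cx3cr1 at 104 against 329 CPM. Sall1, a transcription factor that maintains microglial identity, was at 82.4 against 253 CPM. Genes of the disease-associated microglial state had the opposite direction, with 18 of 20 higher, 0 lower and 2 in neither group (median 2.73 (2.59 to 2.85), percentile 100). They included the growth factor Igf1 (1213 against 113 CPM), the beta-glucan receptor Clec7a (90.6 against 4.85 CPM), the lysosomal protein Cd68 (445 against 22.2 CPM) and the receptor tyrosine kinase Axl (116 against 15.8 CPM).

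By the fixed size rule, the genes with the largest higher values in ICH microglia-like cells were the osteopontin gene Spp1 (NCBI gene 25353; 3189 against 0.255 CPM on 2 control UMIs, 12496-fold (95% interval 3459 to 103186)), Fabp4 (79451; 226 CPM against 0 UMIs, at least 591-fold), Gpnmb (113955; 1301 against 3.32 CPM) and Cd8a (24930; 164 against 0.255 CPM on 2 control UMIs). The galectin gene Lgals3 (83781) was at 1054 against 4.47 CPM and Fcrl2 at 324 against 3.19 CPM. Ifitm1 (346 against 3.70 CPM) did not stand above its level in other classes (background ratio 0.856), and the hexokinase gene Hk3 was at 30.03 CPM against 0 UMIs, at least 78.4-fold. Macrophage genes such as Spp1, Gpnmb and Lgals3 were also counted in neuron-like, pericyte-like, OPC-like or oligodendrocyte-like cells of the ICH library, so part of their counts in microglia-like cells could not be separated from free RNA. Lowest in ICH were the inducible chaperones Hspa1b (108348108; 49.0 against 2731 CPM) and Hspa1a (132 against 3301 CPM), their partners Bag3 (56.1 against 855 CPM) and Hsph1 (75.9 against 977 CPM), the calcium sensor Mctp1 (20.7 against 324 CPM), the hedgehog effector Gli2 (2.35 against 36.5 CPM), the glutamate transporter Slc1a3 (46.5 against 557 CPM) and RT1-CE12 (19.3 against 253 CPM).

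Inflammatory genes of microglia-like cells were split. Of 18 pro-inflammatory genes 3 were higher and 6 lower in ICH (median -0.17 (-0.37 to -0.13)), with the neutrophil attractant Cxcl2 at 916 against 385 CPM and the inflammasome sensor Nlrp3 at 407 against 182 CPM, but Il6 at 8.05 against 45.4 CPM and Tnf at 461 against 946 CPM. Genes that respond to tissue dissociation were also lower in ICH in these cells, as given below. An effect of dissociation on Il6 and Tnf was not separated from that of haemorrhage. Alternative activation genes were higher in 9 of 11 (median 3.52 (3.01 to 3.82); 2.38 in the 9 members above background). Among them were the scavenger receptors Msr1 (203 against 7.27 CPM) and Mrc1 (71.9 against 6.25 CPM). Heme and iron handling genes, which dispose of hemoglobin products, were higher in 11 of 14 (median 1.17 (1.03 to 1.31)), led by heme oxygenase Hmox1 at 933 against 111 CPM. Oxidative stress response genes were higher in 12 of 14 (median 1.47 (1.39 to 1.74)) and phagocytosis genes in 13 of 22 with 2 lower (median 0.81 (0.73 to 0.89)), the lower ones being the efferocytosis receptor Mertk (223 against 672 CPM) and Lamp2. Glycolysis and hypoxia genes were higher in 9 of 17 and lower in 1 (median 1.70 (1.41 to 1.90), or 1.23 in the 6 members above background), with Ldha at 699.5 against 85.1 CPM. Cholesterol synthesis genes were lower in 9 of 16 and higher in 2 (median -0.78 (-0.88 to -0.58)), with 2 members above background.

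Proliferation genes of ICH microglia-like cells were higher in 20 of 24 (median 3.25 (3.01 to 3.41)), including Mki67 at 147 against 15.1 CPM and Top2a at 82.3 against 6.12 CPM. Interferon response genes were higher in 10 of 18 and lower in 1 (median 1.17 (1.01 to 1.31)), but the 9 members that stood above background had a median of 0.45. MHC class II genes were higher in 5 of 9 and lower in 2 (median 1.26 (1.06 to 1.43); 0.71 in the 8 members above background), and MHC class I genes higher in 4 of 10 and lower in 2 (median 0.43 (0.25 to 0.61)). The RT1 genes in these lists are near-identical copies among which short reads can be split, and the haplotypes of the rats are not given in the sources used here, so their single values are uncertain. Immediate early genes, which respond to tissue dissociation, were lower in 13 of 15 (median -1.36 (-1.42 to -1.31); Egr1 728 against 2915 CPM). Genes of other cell types also differed in microglia-like cells, with myelin genes lower in 14 of 14 (median -1.93 (-2.00 to -1.76)) and extracellular matrix genes higher in 13 of 18 (median 1.66 (1.27 to 2.34)), and only 1 member of each list stood above background.

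Other striatal cells were compared to see which of them took on a reactive state after haemorrhage. Control and ICH cells of these classes lay mostly in different clusters, as the microglia-like cells did. Of astrocyte-like cells 949 of 990 were in cluster 23 in control and 435 of 567 in cluster 14 in ICH. Of OPC-like cells 201 of 227 were in cluster 39 in control and 1078 of 1789 in cluster 7 in ICH. For oligodendrocyte-like cells these were 1519 of 2501 in cluster 13 and 503 of 979 in cluster 5. For endothelial-like cells they were 1149 of 1699 in cluster 16 and 195 of 196 in cluster 27. Summed counts weight deep cells more, and part of the ICH cells lay in deeper clusters (medians over all 4 libraries). Cluster 37 held 107 of the ICH astrocyte-like cells at a median of 35324 UMIs, against 3485.5 in cluster 14. Cluster 18 held 540 OPC-like cells of ICH at 19912 UMIs, against 2396 in cluster 7. Cluster 9 held 351 oligodendrocyte-like cells of ICH at 11076 UMIs, against 2148 in cluster 5. In astrocyte-like cells all 17 reactive genes were higher in ICH (median 3.66 (3.24 to 4.62)) and 11 of 14 homeostasis genes were lower (median -1.84 (-1.90 to -1.76)). The intermediate filament gene Vim was at 8909 against 67.6 CPM in them and S100a10 at 1639.7 against 4.42 CPM, while the gap junction gene Gjb6 was at 4.02 against 95.8 CPM and angiotensinogen Agt at 13.7 against 560.1 CPM. All 24 cell cycle genes were higher in astrocyte-like cells (median 4.34 (3.91 to 4.66)) and in OPC-like cells (median 2.42 (2.27 to 3.00)), and OPC-like cells had 20 of 24 matrix genes higher (median 1.87 (1.34 to 1.95)). The Notch effector Hes5 was lower in OPC-like cells (2.18 against 100.2 CPM), as was the potassium channel gene Kcnd2 (31.3 against 1229 CPM), and the calcitonin-related peptide gene Calcb was at 302 CPM against 0 UMIs, at least 83.4-fold. Oligodendrocyte-like cells had 15 of 16 cholesterol synthesis genes lower (median -1.03 (-1.13 to -0.99)) and 6 of 14 myelin genes lower (median -0.36 (-0.39 to -0.35)). Of 10 stress-associated genes 6 were higher and 2 lower in them (median 1.03 (1.01 to 1.06), or 0.30 in the 4 members above background). Zbtb16, a glucocorticoid-responsive transcription factor, was at 55.1 against 292 CPM in oligodendrocyte-like cells and the metalloprotease inhibitor Timp1 at 334 against 2.18 CPM.

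Vascular cells differed in barrier and angiogenic genes. Endothelial-like cells had 9 of 14 blood-brain barrier genes lower and 1 higher in ICH (median -0.71 (-0.75 to -0.61)). Of 16 angiogenic genes 9 were higher and 2 lower (median 0.92 (0.74 to 1.11)), and 4 of 7 leukocyte adhesion genes were higher (median 1.26 (1.09 to 1.42)). The lipid transporter Mfsd2a, which limits transcytosis, was at 33.4 against 97.1 CPM, the tip cell peptide Apln at 486 against 28.7 CPM, Angpt2 at 184 against 32.7 CPM and P-selectin Selp at 65.5 against 4.93 CPM. The basement membrane collagen gene Col15a1 was at 197 against 6.27 CPM. Pericyte-like cells had lower Abcb1a (9.45 against 582 CPM) and Cldn5 (24.8 against 1183 CPM), both endothelial genes, and higher Spp1, at 2917 CPM against 0 UMIs (at least 1495-fold). Of neuron-like cells, 1338 and 1116 of 2491 lay in clusters 15 and 11 in control and 665 of 1032 in cluster 21 in ICH. They had lower serotonin receptor Htr2c (19.7 against 243 CPM) and glycine receptor Glra3 (2.07 against 34.0 CPM), and higher Gpnmb (446 against 0.866 CPM) and Lilrb4 (137 against 0.243 CPM), which are genes of macrophages.

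The next comparison asked whether the injured striatum held other cells after MSC infusion, with the same ICH library as reference for both infusions. Microglia-like cells were 27.0% (26.2 to 27.8) after young MSCs and 19.03% (18.3 to 19.7) after old MSCs, against 15.3% in ICH. The combined share of microglia-like, macrophage-like and cluster 3 cells was 43.2% (42.3 to 44.1) and 45.0% (44.1 to 45.9) against 49.6%, with cluster 3 at 4.19% and 6.41% against 14.6%, in libraries of higher median depth than ICH. Within the microglia-like class, cluster 10, whose leading genes include the stress genes Hspa1a, Hspa1b and Bag3, held 40.8% after young MSCs, 28.6% after old MSCs and 1.73% in ICH. Macrophage-like cells were 12.0% (11.5 to 12.7) after young MSCs and 19.5% (18.8 to 20.3) after old MSCs. The young-to-ICH ratio of macrophage-like shares was 0.610 but 3.32 when each library was clustered alone, so its direction depended on the clustering. Cluster 8 held 94.5% of macrophage-like cells after young MSCs, whereas cluster 1 held 83.0% in ICH and 83.1% after old MSCs. Oligodendrocyte-like cells were 18.1% and 16.6% against 7.62% in ICH, OPC-like cells 8.63% and 8.30% against 13.9%, and fibroblast-like cells 0.995% and 0.822% against 4.24% (3.10% and 2.98% against 7.06% at resolution 0.5). T/NK cell-like cells were 2.00% (1.75 to 2.27) after young MSCs and 0.764% (0.617 to 0.936) after old MSCs against 1.64% (1.43 to 1.88).

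To ask how microglia differed after young MSCs, 3146 microglia-like cells were compared with 1967 of ICH (medians of 7797 and 4690 UMIs). Interferon response genes were higher in 15 of 18 and lower in 0 (median 1.14 (1.06 to 1.22), percentile 100). Among them were the antiviral genes Mx1 (139.9 against 58.2 CPM) and Oasl (236 against 112 CPM), the ubiquitin-like modifier Isg15 (127 against 30.3 CPM), Ifit3 (28.5 against 5.41 CPM) and the transcription factor Irf7 (43.4 against 12.2 CPM). Most of these members were higher still in other classes, and the 5 above background in microglia-like cells had a median of 0.51. MHC class I genes were higher in 2 of 10 (median 0.41 (0.33 to 0.47)), namely the transactivator Nlrc5 (33.1 against 18.2 CPM) and RT1-A2 (1211 against 244 CPM), and MHC class II genes were lower in 3 of 9 (median -0.10 (-0.45 to -0.058)), all of them RT1 genes whose assignment is uncertain. The B cell chemokine Cxcl13 (498335) was at 29.4 against 1.41 CPM. Heat shock genes led the ranking, with Hspa1b at 1653 against 49.0 CPM, Hspa1a at 2211 against 132 CPM, Bag3 at 696 against 56.1 CPM, Hsph1 at 718 against 75.9 CPM and Dnajb1 at 575 against 63.8 CPM, followed by Slc1a3 (487 against 46.5 CPM) and RT1-CE12. The 5 heat shock genes summed were at 5854 CPM here, 376 in ICH and 8506 in control, which had no infusion. Slc1a3 and RT1-CE12 were also higher in control than in ICH. For these leading genes, an effect of the infusion and a low level in the single ICH library cannot be told apart.

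State genes of microglia-like cells moved less with young MSCs. Of 21 disease-associated genes 4 were lower and 0 higher (median -0.18 (-0.20 to -0.089)), the lower ones being the lipase Lpl (29.9 against 62.2 CPM), Ccl6, Cd9 and Spp1 (2021 against 3189 CPM). Homeostatic genes had a median of 0.030 (-0.062 to 0.054) with 2 of 15 lower, pro-inflammatory genes 0.079 (0.040 to 0.10) with 4 of 19 higher (Il12b 43.4 against 25.1 CPM), alternative activation genes -0.19 (-0.42 to -0.11), and cell cycle genes -0.30 (-0.36 to -0.24) with 2 of 24 lower. Oxidative stress response genes were lower in 4 of 14 (median -0.32 (-0.40 to -0.28)), including the quinone reductase Nqo1 (13.9 against 27.2 CPM) and Txnrd1 (67.5 against 128 CPM), and heme handling genes in 3 of 14 (median -0.29 (-0.33 to -0.25)), including the hemoglobin scavenger receptor Cd163 (3.15 against 9.28 CPM). The kynurenine pathway genes Kmo (13.3 against 36.8 CPM) and Qprt (5.18 against 21.6 CPM) were lower by the size rule, together with the phosphatase Ptprm (71.4 against 276 CPM) and RT1-T24-4, and with the kinase Cdk14, Colec12, Rell1 and Dock1, which were not above background. Phagocytosis genes had a median of -0.041, which became 0.024 under median-of-ratios scaling. Myelin genes were higher in 10 of 14 (median 0.89 (0.72 to 0.97)) and matrix genes lower in 13 of 23 (median -0.65 (-0.88 to -0.50)), in step with the larger oligodendrocyte-like and smaller fibroblast-like shares of the infused library, and only 1 member of each list stood above background.

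The same question for old MSCs used 2315 microglia-like cells at a median of 7553 UMIs. Interferon response genes were lower in 1 of 18, Mx1 (29.0 against 58.2 CPM), and higher in 0 (median -0.19 (-0.27 to -0.11); -0.029 in members above background). MHC class II genes were lower in 4 of 9 (median -0.46 (-0.53 to -0.41)), among them the transactivator Ciita (1.45 against 2.76 CPM) and RT1-Bb (3.12 against 58.5 CPM), and MHC class I genes in 2 of 10 (median -0.19 (-0.24 to -0.13)), namely Tap2 and RT1-A1 (69.8 against 166 CPM). Pro-inflammatory genes had a median of 0.30 (0.17 to 0.32) with 2 of 19 higher, and Il1b was at 477 against 341 CPM. Alternative activation genes were lower in 4 of 12 (median -0.27 (-0.38 to -0.11)), including Mrc1 (37.1 against 71.9 CPM) and Clec10a (8.07 against 18.2 CPM), while the anti-inflammatory cytokine Il10 was at 16.6 against 8.17 CPM. Disease-associated genes had 1 of 21 lower (median -0.12 (-0.17 to -0.10)), Lpl at 28.8 against 62.2 CPM, and homeostatic genes a median of 0.15 (0.0013 to 0.21). Heme handling genes had a median of -0.24 (-0.27 to -0.17), phagocytosis genes -0.17 (-0.19 to -0.15), cell cycle genes -0.18 (-0.24 to -0.12) and oxidative stress response genes -0.25 (-0.30 to -0.23).

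By size, the higher genes after old MSCs were again the heat shock genes Hspa1b (1313 against 49.0 CPM), Hspa1a (1810.1 against 132 CPM), Bag3 (482 against 56.1 CPM), Hsph1 and Dnajb1, with Slc1a3 (234 against 46.5 CPM), RT1-CE12 and Adgrl3. The lower genes were the decoy receptor Tnfrsf22 (9.70 against 29.9 CPM), Qprt (8.12 against 21.6 CPM), Ms4a4a (86.5 against 192 CPM), Catip, Adgb, Lpl, RT1-CE16 and RT1-A1, and RT1-CE12, Adgrl3 and RT1-CE16 were not above background. Immediate early genes were higher in 4 of 15 after old MSCs (median 0.40 (0.38 to 0.41)) and in 2 of 15 after young MSCs (median 0.24 (0.23 to 0.26)). Myelin genes were higher in 3 of 14 after old MSCs (median 0.43 (0.35 to 0.51)) and matrix genes lower in 12 of 22 (median -0.77 (-1.03 to -0.57)), as in the other infused library.

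**Figure D2:**
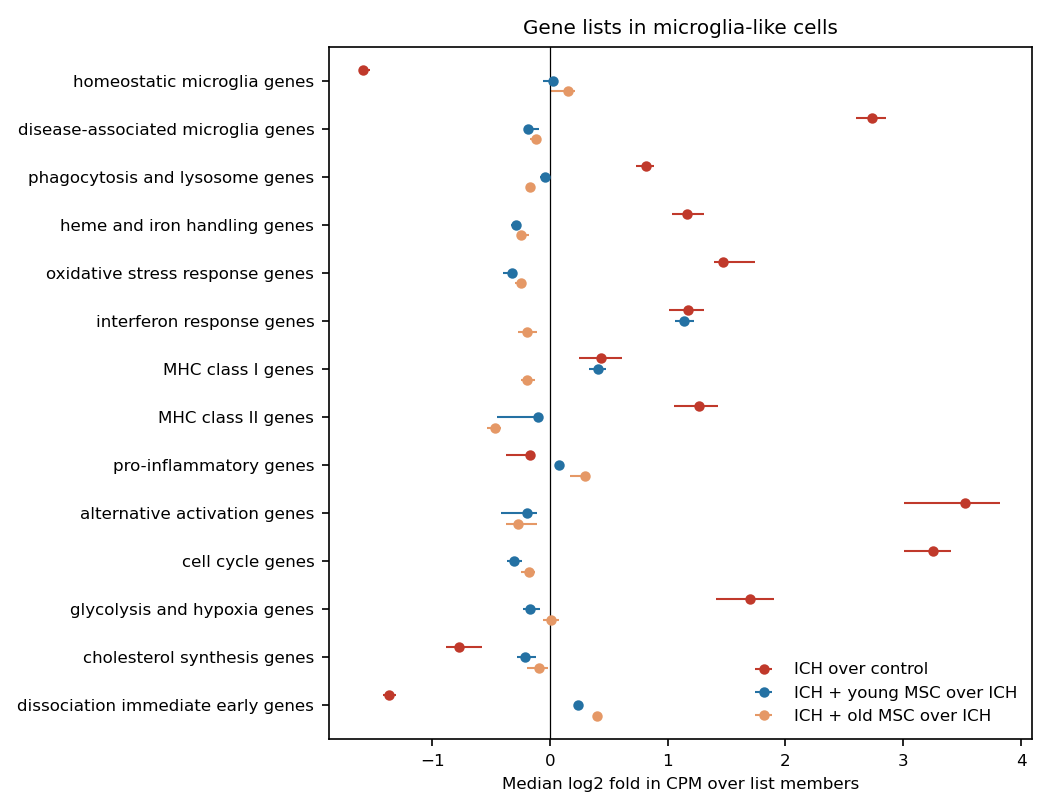
Median log2 ratio (horizontal axis) of 14 gene lists in microglia-like cells for ICH over control and each infused library over ICH. Points are list medians and lines the central 95% of 500 Poisson resamples, and the phagocytosis median for young MSCs changes sign under median-of-ratios scaling.

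Comparing the infused libraries directly asked how microglia-like cells differed between the young and the old MSC infusion. Interferon response genes were higher with young MSCs in 15 of 18 (median 1.10 (1.03 to 1.18); 0.58 in the 5 members above background). MHC class I genes were higher in 6 of 10 (median 0.64 (0.59 to 0.74)), including B2m (3675 against 2404 CPM) and Nlrc5 (33.1 against 13.7 CPM), and MHC class II genes in 3 of 9 (median 0.43 (0.36 to 0.48)), including the invariant chain Cd74 (359.5 against 228 CPM). The size rule named Cxcl13 (29.4 against 1.54 CPM), the co-signalling receptor Tnfrsf14 (24.0 against 2.26 CPM), Slfn4 (218 against 38.0 CPM), Plac8 (180.5 against 37.9 CPM), Mx1 (139.9 against 29.0 CPM), Ifi44l, RT1-A2 and RT1-CE15 as higher with young MSCs. Higher with old MSCs were the semaphorin Sema3c (13.02 against 50.5 CPM), the polyamine enzyme Odc1 (48.0 against 107 CPM), Kcnk10 (57.3 against 122 CPM), Cxcl14, Atg7, S100a4 and Ldhb. Of these genes Mx1, Ifi44l, Sema3c, Odc1, S100a4 and Ldhb were not above background. Il10 was at 7.59 against 16.6 CPM and Tnf at 439 against 582 CPM. Disease-associated genes (median -0.10 (-0.16 to -0.056)), pro-inflammatory genes (-0.017 (-0.054 to 0.026)) and homeostatic genes (-0.12 (-0.21 to -0.10)) had smaller differences. Among genes foreign to microglia, 1 of 14 myelin genes was higher with young MSCs and 0 lower (median 0.50 (0.38 to 0.55)), and 7 of 22 matrix genes were higher and 3 lower (median 0.24 (0.10 to 0.45), −0.073 at a minimum of 200 UMIs).

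Macrophage-like cells were compared to ask whether they followed the same pattern as microglia-like cells. With young MSCs, 17 of 18 interferon response genes were higher than in ICH (median 1.90 (1.83 to 1.96)), with Ifit3 at 89.6 against 4.79 CPM, Irf7 at 116 against 13.3 CPM and Mx1 at 149 against 18.5 CPM, whereas with old MSCs 3 were lower and 0 higher (median -0.26 (-0.35 to -0.12)). Young MSCs went with higher Nos2 (76.1 against 21.8 CPM), Ccl5 (12.99 against 2.19 CPM) and Slfn4 (211 against 18.9 CPM), and with lower Selenop (352 against 873 CPM) and Apoc4. The pro-inflammatory median of 0.29 became −0.21, and the heme handling median of -0.10 became 0.61, when only cluster 8 was used in both libraries. MHC class I genes had medians of 0.47 (0.42 to 0.52) with young and -0.10 (-0.19 to -0.045) with old MSCs (0.023 in members above background). Old MSCs went with lower MHC class II genes (5 of 9, median -0.62 (-0.69 to -0.60)), among them Cd74 (502 against 772 CPM), and with lower complement genes C1qa (515 against 885 CPM) and C1qc (194 against 417 CPM). The iron exporter Slc40a1 (5.86 against 21.6 CPM), Ms4a7 (11.5 against 43.5 CPM) and Il20rb were also lower with old MSCs. The hepatocyte growth factor receptor Met was higher in both, at 61.6 against 5.44 CPM with young and 59.8 against 5.44 CPM with old MSCs. Between the infused libraries MHC class II genes were higher with young MSCs (median 0.49), but the median was −1.83 in cluster 8 alone.

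Interferon response genes were then followed across cell classes with at least 100 cells. Their median was above 0 in all 12 classes for young MSCs over ICH, from 0.70 in dendritic cell-like to 3.11 in neutrophil-like cells. For old MSCs over ICH it was above 0 in 4 and below 0 in 7 of 11 classes, from −0.66 in OPC-like to 0.56 in neutrophil-like cells. Young over old was above 0 in 11 of 11 classes. With members above background in at least 3 genes, 8 of 8 classes were above 0 for young MSCs (0.51 to 3.12) and 4 of 8 for old MSCs (−0.31 to 0.83). The antiviral and chemokine genes named by size with young MSCs were Cxcl10 (369 against 12.4 CPM), Mx1 and Isg15 (418 against 21.7 CPM) in astrocyte-like cells, Mx1 (153 against 9.02 CPM) and Rsad2 (22.3 against 1.20 CPM) in OPC-like cells, Isg15 in endothelial-like (392.1 against 66.9 CPM) and pericyte-like cells (951 against 92.1 CPM), Mx1 in fibroblast-like cells (39.2 against 3.84 CPM), and Ifit2 (590.0 against 32.9 CPM) in neutrophil-like cells. Of these, Isg15 in astrocyte-like and endothelial-like cells, both genes in OPC-like cells, Mx1 in fibroblast-like cells and Ifit2 in neutrophil-like cells were not above background. MHC class I medians were above 0 in 12 of 12 classes for young MSCs and below 0 in 9 of 11 for old MSCs.

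**Figure D3:**
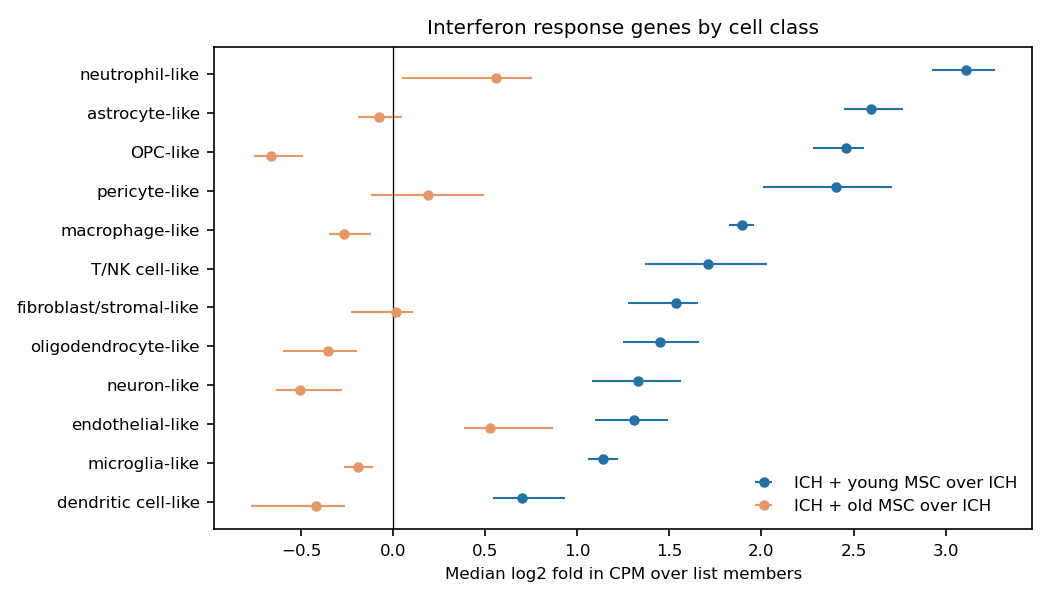
Median log2 ratio (horizontal axis) of interferon response genes in each cell class for young and old MSC infusion over ICH. Points are list medians and lines the central 95% of 500 Poisson resamples, and classes under 100 cells in a library have no point.

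Beyond interferon genes, the remaining classes were searched for genes that set each infused library apart from ICH. T/NK cell-like cells of the young MSC infusion had the granzyme Gzma at 406 against 31.6 CPM and lower Tnfsf8 (23.9 against 150.3 CPM) and lymphotoxin Lta (5.97 against 49.0 CPM). Dendritic cell-like cells had lower Ccl22 with young MSCs (11.5 against 91.7 CPM) and lower Ccl17 with old MSCs (3.55 against 169.8 CPM), both chemokines that attract T cells. Astrocyte-like cells of the old MSC infusion had the siderophore-binding protein Lcn2 at 213 against 25.2 CPM and the protease inhibitor Serpina3n at 3.40 against 68.5 CPM, and those of the young MSC infusion had lower Lcat (34.6 against 109 CPM). Endothelial-like cells had higher Sox18 (66.8 against 14.7 CPM) and lower Cxcl11 (183 against 606 CPM) with old MSCs and lower Thsd7b with young MSCs (18.6 against 196 CPM). OPC-like cells had the neuropeptide genes Vgf (272 against 91.4 CPM) and Gal (234 against 82.1 CPM) higher with old MSCs and Cxcl14 lower with young MSCs (45.4 against 172 CPM). Neuron-like cells lay in different clusters, 665 of 1032 in cluster 21 in ICH and 866 of 1430 in cluster 12 after young MSCs. They had the dopamine receptor Drd2 (163 against 28.4 CPM) and Pde1c (136 against 22.7 CPM), both genes of striatal projection neurons, higher with young MSCs. Cluster 21 had 6 detected neuron markers and cluster 12 had 12. Another neuron-like cluster, 32, held 54 cells in ICH, 0 after young and 407 after old MSCs. A difference in which neurons were sampled therefore cannot be separated from a difference within them. Pericyte-like cells had lower Ccl7 with young (52.6 against 348 CPM) and old MSCs (31.5 against 348 CPM), and neutrophil-like cells had lower Ccl2 with young MSCs (1082 against 4017 CPM). Fibroblast-like cells had higher pentraxin Ptx3 with young MSCs (63.3 against 8.63 CPM) and Ccl20 at 0 UMIs with old MSCs against 23.4 CPM, at least 21.8-fold lower.

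The old and young MSCs were compared to ask how the infused cells differed with donor age, with 6737 old and 7560 young cells (24 old cells with myeloid markers were left out). The median gene was 0.11 log2 units lower in old MSCs, and 0.00 after median-of-ratios scaling, and relative to it the glycolysis and cell cycle medians below are 1.49 and -1.25. Glycolysis and hypoxia genes were higher in old MSCs in 16 of 19 and lower in 0 (median 1.38 (1.35 to 1.40), percentile 100), with Pgk1 at 1099.5 against 293 CPM, Ldha at 911 against 308 CPM and the oxygen-sensing hydroxylase Egln3 at 9.99 against 0.124 CPM. The leading genes by size included the mitochondrial subunits Ndufa4l2 (100362331; 140.1 against 1.03 CPM, 136-fold (95% interval 118 to 157)) and Cox4i2 (26.6 against 0.854 CPM), the lactate exporter Slc16a3 (36.5 against 1.38 CPM), the mitophagy receptor Bnip3 (385 against 35.2 CPM) and the lipolysis inhibitor G0s2 (289388; 359 against 13.9 CPM). The growth factor Vegfa was at 263 against 101 CPM. Cell cycle genes were lower in 21 of 24 (median -1.36 (-1.43 to -1.32), percentile 0), including Top2a (6.94 against 27.2 CPM), Mki67 (7.83 against 29.9 CPM) and Cenpf (11.7 against 46.4 CPM), and cycling clusters held 486 young and 2 old cells in cluster 11 and 0 young and 96 old cells in cluster 12. In cells outside the cycling clusters the cell cycle median was −0.96.

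Chemokine genes also set old MSCs apart, while growth factor and matrix genes went both ways. Chemokine genes were higher in 8 of 16 and lower in 2 (median 0.59 (0.40 to 0.94)), with the monocyte attractants Ccl7 (960.0 against 184 CPM) and Ccl2 (616 against 206 CPM), Cxcl12 (336 against 158 CPM) and Ccl20 (45.1 against 3.47 CPM). Growth factor genes were split, 5 higher and 7 lower of 20 (median -0.38 (-0.42 to -0.33)), with Hgf at 1.30 against 7.88 CPM, Bdnf at 2.42 against 12.6 CPM and Fgf10 at 30.8 against 8.78 CPM. Higher by size were the matrix protein Abi3bp (333 against 19.1 CPM), the lipopolysaccharide-binding protein Lbp (68.6 against 6.52 CPM), Cntnap5c, Abca4, Lce1m and Parm1. Lower by size were the heparin-binding cytokine Ptn (24924; 20.8 against 281 CPM), Itm2a (2.99 against 44.0 CPM), the glypican Gpc3 (7.65 against 78.4 CPM), the imprinted RNA Meg3 (26.8 against 221 CPM), the GDNF receptor Gfra1 (4.00 against 33.4 CPM), Spp1 (4.35 against 35.4 CPM), the thyroid hormone deiodinase Dio3 (3.86 against 24.7 CPM), Hdac9, Ccdc103, Frmd5, Ldb2 and Pear1. Extracellular matrix genes had 9 of 24 lower and 4 higher (median -0.20 (-0.21 to -0.19)), contractile genes 6 of 12 lower (median -0.60 (-0.61 to -0.59); Acta2 235 against 524 CPM) and cholesterol synthesis genes 8 of 16 lower (median -0.58 (-0.61 to -0.57)). Adipogenic genes were lower in 4 of 10 and higher in 1 (median -0.39 (-0.55 to -0.33)) and osteogenic genes lower in 4 of 8 (median -0.44 (-0.65 to -0.079)), and surface genes had a median of 0.091 (0.063 to 0.12).

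Age-related and immune lists of the MSCs were less uniform. Senescence genes were higher in 6 of 18 and lower in 2 (median 0.23 (0.20 to 0.25)), with Igfbp3 at 798 against 103 CPM but the cell cycle inhibitors Cdkn2a at 31.2 against 77.9 CPM and Cdkn2b at 15.1 against 60.2 CPM. Interferon response genes were lower in 11 of 18 (median -0.67 (-0.86 to -0.52)), many at under 1 CPM in each library, and MHC class I genes lower in 5 of 10 and higher in 2 (median -0.56 (-0.71 to -0.51)), among them the immunoproteasome gene Psmb9 (15.3 against 34.0 CPM). Heme handling genes were higher in 4 of 13 (median 0.37 (0.25 to 0.43); Hmox1 260.2 against 100.4 CPM, ferritin light chain Ftl1 725 against 118 CPM) and oxidative stress response genes in 4 of 15 (median 0.24 (0.20 to 0.28)). Immunomodulatory genes (median -0.080) and matrix protease genes (-0.026) changed sign under median-of-ratios scaling, to 0.031 and 0.085. Markers of myeloid cells were higher in old MSCs in 7 of 7 (median 1.23 (0.91 to 1.94)) even after marked cells were left out. Nearly all MSC clusters were of 1 library each, the exception being cluster 9 with 486 young and 120 old cells at a median of 3418 UMIs.

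**Figure D4:**
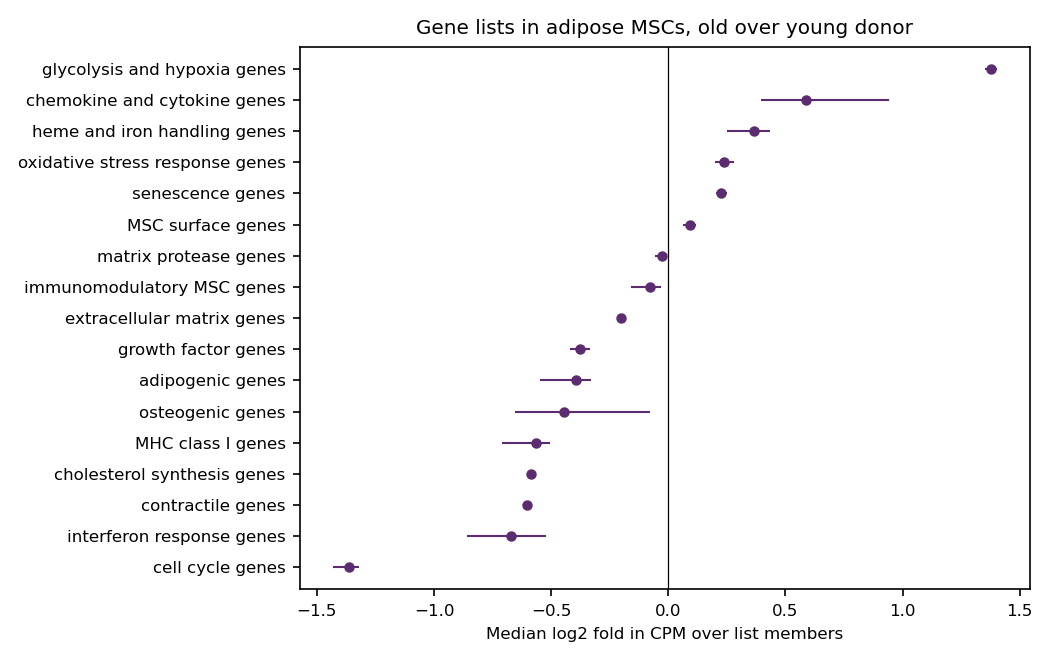
Median log2 ratio of old over young MSCs (horizontal axis) for 17 gene lists. Points are list medians and lines the central 95% of 500 Poisson resamples, and the immunomodulatory and matrix protease medians change sign under median-of-ratios scaling.

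The study title names Csf1 in the infused cells, so Csf1 (NCBI gene 78965), the growth factor that sustains microglia, was followed as a gene chosen by the study and not as independent evidence. MSCs had Csf1 at 141 CPM when young and 116 CPM when old, 1.21-fold (95% interval 1.19 to 1.24) lower in old cells, and its receptor Csf1r (307403) at 0.288 and 0.479 CPM. The log2 ratio of Csf1 was −0.28 (−0.31 to −0.25). It shrank to −0.17 under median-of-ratios scaling and under the mean of per-cell CPM, outside that interval. After thinning to 5000 UMIs per cell, 46.8% (45.6 to 47.9) of 7163 young MSCs and 40.6% (39.4 to 41.9) of 6277 old MSCs had a Csf1 UMI, leaving out 397 and 460 shallower cells. Without thinning the shares were 85.0% and 74.4%, at median depths of 24446 and 19791 UMIs. In the striatal libraries Csf1 was at 29.3 CPM in control, 93.4 in ICH, 112 with young MSCs and 103 with old MSCs, and the alternative receptor ligand Il34 at 20.8, 7.67, 9.89 and 8.40 CPM. Microglia-like cells held 30.4% of Csf1 UMIs in ICH, 47.3% with young and 39.7% with old MSCs, and macrophage-like cells 47.2%, 26.7% and 38.4%, whereas oligodendrocyte-like cells held 35.0% in control.

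Within microglia-like cells Csf1 was at 195 against 82.8 CPM in ICH against control (2.35-fold (95% interval 2.16 to 2.56)), at 199.7 CPM with young MSCs and at 247 CPM with old MSCs (1.27-fold (95% interval 1.21 to 1.32) over ICH). Csf1r was at 618 against 1015 CPM in ICH against control, and at 558 CPM with young and 561 CPM with old MSCs. A Csf1 UMI was found in 16.8% of control microglia-like cells, 37.6% in ICH, 45.0% with young and 43.4% with old MSCs, at median depths of 5771, 4690, 7797 and 7553 UMIs. Endothelial-like cells, taken as a type with little Csf1, had one in 3.77%, 12.2%, 13.4% and 10.2%, at 2640, 3548.5, 5559 and 3842 UMIs. Of the CSF1 receptor axis genes 5 of 11 were higher in ICH microglia-like cells and 1 lower (median 0.41 (0.32 to 0.51)), with the GM-CSF receptor chain Csf2ra at 179.8 against 13.7 CPM. Those genes had medians of 0.053 (0.024 to 0.091) with young and 0.046 (-0.0043 to 0.059) with old MSCs over ICH. In macrophage-like cells Csf1 was at 110.4 CPM in ICH, 121 with young and 102 with old MSCs, and neutrophil-like cells had 234, 171 and 300.5 CPM.

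**Figure D5:**
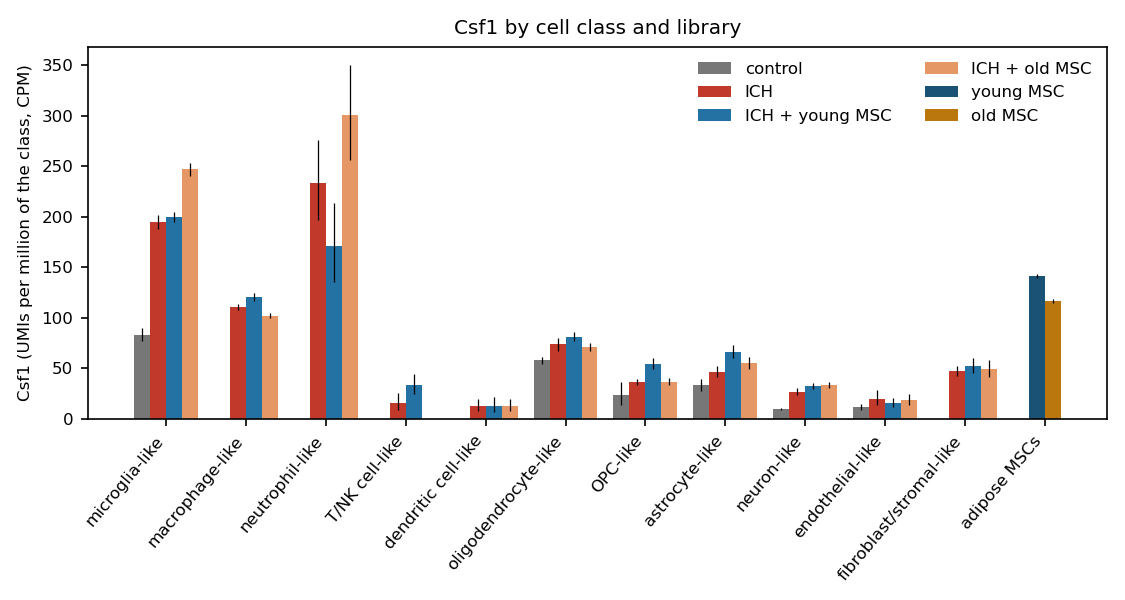
Csf1 level (CPM of summed counts, vertical axis) by cell class and library, with the infused cell types beside the striatal classes. Bars are 1 library each for classes of at least 100 cells and lines are exact 95% Poisson intervals.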

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

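The tests of explanations in this part were chosen only after the result was seen. Results were taken up here because the differences of the infused libraries from the same ICH library went opposite ways. In microglia-like cells the interferon response median was 1.14 (1.06 to 1.22) with young MSCs and −0.19 (−0.27 to −0.11) with old MSCs, and the MHC class I median 0.41 (0.33 to 0.47) and −0.19 (−0.24 to −0.13). In macrophage-like cells the interferon median was 1.90 (1.83 to 1.96) and −0.26 (−0.35 to −0.12), and the MHC class I median 0.47 (0.42 to 0.52) and −0.10 (−0.19 to −0.04), the last being 0.023 in members above background. The ratio of T/NK cell-like shares to ICH was 1.22 (1.00 to 1.47) with young and 0.465 (0.361 to 0.597) with old MSCs. With 1 library per group the gap between these differences was not tested, and the shared ICH library ties them together.

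The pattern weighed was the higher level of interferon response genes after young MSCs, above 0 in 12 of 12 classes. RNA of the infused cells themselves is excluded, since for the median of the 15 members higher in microglia-like cells the young MSC library would have to make up 1932% of the RNA (1.68% for the lowest member), while Y-linked UMIs allow at most 0.0896%. Free RNA spread evenly from 1 class is excluded as the sole cause. The rise in list UMIs per cell went from 1.71 in oligodendrocyte-like to 71.8 in fibroblast-like cells, a ratio of 42.1 (at least 37.9). The deepest striatal library, that of old MSCs, had a median of −0.19 in microglia-like cells. That value also served to pick the pattern, and microglia-like cells were deeper with young than with old MSCs (medians of 7797 and 7553 UMIs). It therefore cannot decide on deeper sequencing. Fibroblast-like cells were deeper in the young MSC library, at a mean of 32550 against 13418 UMIs, which enters their rise and the ratio. The bound covers counting error only. Astrocyte-like cells, at means of 10402 and 9650 UMIs, rose by 25.3. A difference in donor age of the infused cells stays open and untested, as does a state of the single recipient rat, and either may underlie the pattern. Where only microglial members above background are used, the median of 0.51 is lower than the 1.14 over all members, so part of it in those cells could be RNA from other classes.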

How the results depend on the processing

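No paired analysis was possible because each group has 1 library. The alternatives on doublets at the expected rate, named cells only, cluster 3, cluster 8, cells of at least 5000 UMIs, members above background and the partition of lowest modularity were chosen only after the result was seen. For all values below the cause was not tested.

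With each library clustered alone, the macrophage-like share of young MSCs over ICH was 3.32 in place of 0.610, a change of direction, that of old MSCs over ICH 1.47 in place of 0.990, the microglia-like share of ICH over control 1.48 in place of 1.67 and of young MSCs over ICH 1.47 in place of 1.76, and the pericyte-like share of old MSCs over ICH 0.960 in place of 1.84. At resolution 2 the first was 0.417 and microglia-like ICH over control 1.55. With at least 1000 genes per cell the macrophage-like ratios were 0.544 and 0.911, microglia-like ICH over control 1.499, and ratios that changed direction were astrocyte-like young over ICH (0.991, from 1.14) and neutrophil-like young (1.23, from 0.523) and old over ICH (1.33, from 0.764), a class of shallow cells. With doublets removed at the expected rate the macrophage-like ratios were 0.467 and 0.744 and the microglia-like ones 1.504 (ICH over control) and 1.65 (young over ICH). Among named cells only they were 0.545 and 0.898, with microglia-like 1.57 (young) and 1.13 (old over ICH), and with cluster 3 added 0.473 and 0.757.

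In microglia-like cells median-of-ratios scaling gave −1.45 for homeostatic and 2.87 for disease-associated genes (ICH over control), −0.047 for disease-associated genes with old MSCs and, with a change of sign, 0.024 for phagocytosis genes with young MSCs. The mean of per-cell CPM gave −1.04 and 2.42 (ICH over control), −0.21 and −0.20 for disease-associated and 1.27 and −0.053 for interferon genes (young and old over ICH), 1.02 for interferon genes (young over old) and 0.027, reversed, for cell cycle genes (young over old, −0.045 before). A minimum of 200 UMIs reversed matrix genes to −0.073 (young over old), and the reduced denominator gave −1.47 for homeostatic genes. At most 10% mitochondrial UMIs gave −1.42 for homeostatic genes, −0.22 and −0.20 for disease-associated genes (young and old over ICH) and, young over old, 0.93 for interferon and 0.20, reversed, for cell cycle genes. Doublets removed at the expected rate gave −1.40 and 2.58 (ICH over control), −0.26 for disease-associated and 1.05 for interferon genes (young over ICH) and, young over old, 0.99 for interferon genes and, reversed, 0.085 for cell cycle and 0.11 for oxidative stress genes. Cells of at least 5000 UMIs gave −1.63 for homeostatic genes. Members above background gave interferon medians of 0.51 (young over ICH), −0.029 (old over ICH) and 0.58 (young over old).

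In macrophage-like cells, cluster 8 alone changed the sign of 7 values, to −0.21 for pro-inflammatory and 0.61 for heme genes (young over ICH), 0.024 for Csf1 (old over ICH) and, young over old, 0.61 for disease-associated, −0.18 for pro-inflammatory, −0.088 for alternative activation and −1.83 for MHC class II genes. In MSCs median-of-ratios scaling gave −1.25 for cell cycle genes, 1.49 for glycolysis genes, −0.17 for Csf1 and, reversed, 0.031 for immunomodulatory and 0.085 for matrix protease genes, the mean of per-cell CPM −1.46, 1.44 and −0.17 for the same leading 3, and cells outside cycling clusters −0.96 for cell cycle genes.

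Over all alternatives, 425 of 640 class shares, 319 of 390 ratios of shares, 517 of 668 list medians and 536 of 648 named genes in microglia-like cells, 62 of 89 list medians and 106 of 129 named genes in MSCs stayed within their counting interval, as did 4 of 4 shares with Csf1. Of the 24 list medians and 17 genes in macrophage-like cells, 2 and 4 did. Depth limits shallow classes such as neutrophil-like cells and the interferon members near background.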

Other observations

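The tests of explanations in this part were chosen only after the result was seen, and so were the genes and clusters described.

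Several smaller cell groups and gene families went beyond the comparisons above. A small unnamed cluster had the osteoclast genes Ctsk, Mmp9, Acp5 and Atp6v0d2 as leading genes and held 0 control cells, 72 ICH cells, 49 with young and 31 with old MSCs, at a median of 1001.5 UMIs. Dendritic cell-like cells after old MSCs had the mast cell and basophil proteases Mcpt2 (327 CPM), Mcpt8 (241 CPM) and Mcpt9 (112 CPM), each against 0 UMIs in ICH. In oligodendrocyte-like cells after young MSCs the glucocorticoid-responsive genes Fkbp5 (202 against 28.4 CPM) and Zbtb16 (454 against 55.1 CPM) were higher than in ICH, Fkbp5 without standing above background. Zbtb16 was also higher in control than in ICH in these cells. For this gene the infusion and the single ICH library therefore cannot be told apart. Copies of the RT1 family differed between libraries in several classes at the same time. RT1-CE12 was higher after both infusions than in ICH in microglia-like (199 and 121 against 19.3 CPM), endothelial-like (151 and 105 against 21.4 CPM) and fibroblast-like cells (103 and 67.8 against 10.0 CPM), without standing above background in endothelial-like cells or, after old MSCs, in microglia-like cells. RT1-Bb was lower after old MSCs in microglia-like (3.12 against 58.5 CPM), macrophage-like (6.17 against 231 CPM) and dendritic cell-like cells (216 against 3464 CPM). Choroid plexus-like cells, from outside the striatum, were 7.39% of control (32.5% at resolution 0.5), 0.576% of ICH and 1.00% after old MSCs, with 0 to 7 cells after young MSCs over the settings.

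Heat shock genes were lower in the ICH library than in the other striatal libraries, with 376 CPM in microglia-like cells against 8506 in control, 5854 with young and 4557 with old MSCs for 5 genes summed. Control, without infusion, was also higher than ICH, by a median of 3.93 log2 units over the 5 genes (at least 3.84). This is part of the pattern itself, so it cannot decide whether infusion raised these genes over ICH. A dissociation response of all cell classes that spared the ICH library was weighed with immediate early genes other than Hspa1a and Hspa1b. Their median was higher in ICH than in control by 0.91 in astrocyte-like cells (at least 0.78) and above 0 in 4 of 7 classes. Control and ICH also differ by the haemorrhage, so this comparison cannot decide. The median was below 0 in 10 of 12 classes over young MSCs and 9 of 11 over old MSCs. Its counting interval lay above 0 in 1 class over young and 1 over old MSCs. A response of this kind across all classes is therefore neither excluded nor shown. Such a response of microglia-like cells is consistent with their 3 medians, which were all below 0, the highest being −0.23 over young MSCs (counting interval −0.25 to −0.21, 13 genes) beside −1.25 over control and −0.39 over old MSCs. The agreement is in sign only, since the heat shock medians were −3.63 over young MSCs, −3.93 over control and −3.10 over old MSCs, which is larger in size and in another order. Handling of the single ICH rat and a state of that rat cannot be told apart, because the ICH library was lowest in 14 of 14 classes and no other untreated ICH library exists in the design to compare with. The higher heat shock genes after infusion, and the microglia-like cluster 10 whose leading genes include them, therefore stay open.

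The striatal libraries are labelled male, but Xist, which is expressed from the inactive X chromosome of females, was at 887 CPM in control, 585 in ICH, 672 with young and 549 with old MSCs, and 4 Y-linked genes together had 24, 10, 11 and 14 UMIs. In the young MSC library the 4 genes together were at 182 CPM (at least 180.2). Eif2s3y, Kdm5d and Uty were at 65.6, 23.9 and 92.6 CPM there, so a reference that does not count them is excluded. For Ddx3y, at 0.0566 CPM there, it is not excluded. A single mislabelled library is excluded because 4 of 4 striatal libraries had Xist above 100 CPM. Female rats in all striatal libraries are consistent with a highest share of 0.155% of cells with a Y-linked UMI, against 93.4% of young MSCs. These shares are at unlike depth, since striatal cells had medians from 3947.5 (control) to 6242 UMIs (old MSCs) against 24446 in young MSCs. In CPM the Y-linked genes were at 0.232 in control and lower in the other striatal libraries. No biological explanation other than the sex of the rats was tested. The MSC libraries had Xist at 0.185 and 0.321 CPM, so infused male cells in female recipients could be seen by Y-linked UMIs. Of the striatal cells, 0 had 2 or more Y-linked UMIs, a number that shallow male cells can miss.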
